A study of Mus musculus with 4 samples.

How the data were processed

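Single-cell RNA profiles came from the stromal vascular fraction of abdominal white fat, the cells left when the fat cells themselves are removed. The animals were 5 old female C57BL/6 mice, 25 to 30 months of age, that carry a p21-Cre transgene, whose green fluorescent protein (GFP) reports activity of the promoter of p21, the cell cycle inhibitor encoded by Cdkn1a. Per the labels' protocols, the cells of each donor were tagged, the donors were pooled, and the pool was then sorted into GFPhigh and non-GFPhigh cells, with cells of wildtype mice setting the gate. Per the same protocols each sorted population went into 1 droplet lane, at most 12000 cells loaded and 6000 targeted at 50000 reads per cell, so lane and population cannot be separated by any test here. The tissue label names an epididymal depot although the mice are female, so the depot is called visceral fat throughout.

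The deposited RNA matrices hold raw UMI counts, each count being 1 unique molecule per gene and droplet barcode, made by the authors with Cell Ranger 4 per the file headers. The submitters' processing notes name bcl2fastq 2.20.0.422, Seurat 4.2.0 and the GRCm38 (mm10) mouse genome. The gene annotation behind the counts and any filter by the authors are not given in the sources used here. The matrices list 3611869 barcodes for the non-GFPhigh and 3522290 for the GFPhigh lane, empty droplets included, with 196788423 and 249350599 UMIs over 32285 genes. Barcodes with at least 1000 UMIs numbered 15703 and 17112, more than the 6000 cells targeted and the 12000 loaded at most per lane, so more than 1 lane per population cannot be ruled out. Genes are named by the symbols in those files. GFP and Cre are not among the genes analysed here, so the sort itself was checked through Cdkn1a mRNA alone.

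The RNA matrices also hold counts of 12 multiplexing tags. The same 5 tags carried at least 13677034 UMIs each in both lanes, the others at most 674, and each of the 5 was taken as 1 mouse, which is an inference from the values, as no source names a tag's mouse. Separate hashtag count matrices were not used, because only 1.14% and 1.13% of the cell barcodes occurred in them, against 1.11% and 1.14% for unrelated barcodes, and because they name 4 hashtags for 5 mice. Tags were called with HTODemux in Seurat 5.3.0 at a quantile of 0.99, per lane. A cell had at least 1000 UMIs, at least 500 genes, at most 10% mitochondrial UMIs and a single tag. Of 14406 and 14532 barcodes past the first 3 limits (non-GFPhigh, then GFPhigh), 13.6% and 8.72% carried 2 tags and 18.7% and 23.0% carried none. Doublets of cells with the same tag were expected at 3.89% and 2.34%. The automatic threshold of Scrublet (scanpy 1.11.5) marked 3.00% and 0% of barcodes, so in the GFPhigh lane the highest-scoring 2.34% of singlets were removed in its place. That step removed 152 and 229 cells and left 9602 non-GFPhigh and 9689 GFPhigh cells with 110984961 and 132805743 UMIs. Kept cells had a median of 9996.5 and 12426 UMIs and of 2898 and 3301 genes.

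The cells of both lanes were clustered together (2000 variable genes, 40 principal components, 15 neighbours, Leiden clustering at resolution 1 with leidenalg 0.10.2), without any correction between lanes. Each of the 43 clusters was named from 22 marker lists fixed before the data were examined. A name needed at least 3 markers detected in at least 25% of the cluster's cells and a mean log2 excess of the markers over all clusters of at least 2.2. A cluster that also carried 8 or more detected markers of an unrelated class within 1.5 of its own score stayed unnamed. These score limits were set while looking at the clusters, before any comparison between populations. They and the rule on shallow clusters left 4 clusters unnamed, holding 2.80% of non-GFPhigh and 3.97% of GFPhigh cells. All class names below stand for marker-defined, X-like classes: "stromal" means adipose stromal-like, and so on. The leading genes were Dpt, Clec3b, Lum and Pdgfra in stromal clusters, Gpihbp1, Cldn5 and Cdh5 in blood endothelial clusters, C1qa, Mrc1 and Pf4 in macrophage clusters, Chil3 and Ms4a4c or Ear2 and Adgre4 in the monocyte clusters, Ms4a1 and Cd79a in B cell clusters, and Upk3b and Gpm6a in the mesothelial cluster. Some clusters were led by other genes: Saa3, Cxcl5 and Timp1 in stromal cluster 16, Mki67 and Top2a in macrophage cluster 20, and histone genes in T cell cluster 39.

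UMI counts were summed per mouse, population and class. A mouse entered a class comparison with at least 20 cells in both populations, and a class was tested with at least 3 such mice. This gave 6 tested classes, ranked by cells in the smaller population: stromal and blood endothelial cells (5 mice), monocytes (mice 1, 3, 4 and 5), B cells (mice 1, 2, 3 and 5), macrophages (mice 1, 3 and 5) and mesothelial cells (mice 1, 2 and 3). Summed libraries of all cells held 7618821 to 40439398 UMIs. The lowest class library held 2415000 UMIs in stromal cells, 305980 in endothelial cells, 166440 in monocytes, 271610 in B cells, 417470 in macrophages and 400120 in mesothelial cells. GFPhigh and non-GFPhigh sums were compared with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr) with mouse as a block, and p was adjusted by Benjamini-Hochberg at 0.05. Log2 fold changes are GFPhigh over non-GFPhigh, ± their standard error. Levels are CPM (UMI counts scaled to the library total) after TMM scaling, as means over mice ± SD, except that levels of Cdkn1a compared between classes are CPM without TMM. The block follows the protocol, in which each donor gave cells to both populations. The sample titles speak of GFP negative and GFP positive mice, which leaves the pairing in some doubt. As a check, the deviations of a mouse's 2 libraries from their population means correlated across genes with a mean r of 0.423 in all cells (lowest mouse 0.341), 0.424 in stromal cells (0.143), 0.247 in endothelial cells (0.13), 0.309 in monocytes (0.061), 0.476 in B cells (0.335), 0.284 in macrophages (0.209) and 0.359 in mesothelial cells (0.252). Each library correlated best with that of its own mouse.

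A set of 24 gene lists, fixed before the data were examined, was tested in each class with camera in limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, which asks whether a list's genes move one way on balance. A list is said to be called by camera at the preset correlation. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. Shares of classes were tested with the same edgeR model on cell numbers, for classes with at least 30 cells, with an exact two-sided sign-flip test over mice beside it. A model with an interaction term asked which genes changed by different amounts in stromal and endothelial cells. Shares of cells with a Cdkn1a UMI were compared after each cell was thinned to 1000 UMIs. Intervals of pooled shares are exact binomial 95% intervals and cover counting error only. Gene counts per class and their p-values rest on 3 to 5 animals.

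Genes named in the text followed a rule fixed before the data were examined. For stromal cells, endothelial cells and monocytes these were Cdkn1a and the 8 higher and 8 lower genes with the largest log2 fold change among genes past the threshold with the same sign in every mouse and at least 20 CPM in the higher population, and up to 4 members with the smallest p of each described list. Lists were described where camera called them, and in those 3 classes also the p53, senescence-associated secretory phenotype (SASP), CDK inhibitor, proliferation and immediate early lists. For other classes and for all cells the rule took Cdkn1a and 3 genes in each direction. Ribosomal protein, mitochondrial, Gm and Rik genes were counted and not named. Where a population held no UMI of a gene, the fold is given as a lower bound against a floor of 3 UMIs over that population, and with 1 to 3 UMIs as the ratio of UMI rates with its exact 95% interval.

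On simulated counts drawn from the real means, library sizes and spreads with a seeded set of genes changed by known folds, the test recovered 93.8% of 4-fold changes in all cells, 98.5% in stromal cells, 100% in endothelial cells and monocytes, 98.4% in B cells and mesothelial cells and 73.8% in macrophages. For 1.5-fold changes it recovered 17.9% in all, 62.7% in stromal, 46.2% in endothelial, 19.7% in B and 25.4% in mesothelial cells, 20.0% in monocytes and 7.58% in macrophages. Of the simulated calls, 23.4% of 94 were false in macrophages and 9.04% of 188 in stromal cells, above the nominal 5%, and 1.67 to 7.69% in the others. These shares vary with the number of genes changed and need not hold for real calls.

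RNA of macrophages in other classes was estimated per mouse from 13 fixed macrophage markers, as the share of a summed library that would carry them if it had the profile of that mouse's GFPhigh macrophages. In mesothelial cells the estimate is too high, because they hold 1 of the markers, Trem2, near the level of macrophages. Free RNA was profiled from 140910 and 171937 barcodes of 20 to 300 UMIs and its share estimated from markers of absent classes. Alternatives were the Wald test of DESeq2 1.42.0, DESeq2 size factors, no filter or at least 10 counts in every library, free RNA subtracted, no block, each mouse left out, other limits on UMIs, genes and mitochondrial share, tag calls by a ratio of 3 with at least 10 UMIs, Scrublet doublets kept, at least 50 cells per sum, and each cell thinned to 1000 UMIs. Subtraction of the macrophage profile and cluster as a term (counts summed per mouse, population and cluster) were added after the data were examined. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3, ran the rest.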

Results

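RNA was counted in single cells of visceral fat from 5 old female p21-Cre mice, sorted by green fluorescence into a GFPhigh and a non-GFPhigh population. By the protocol each mouse gave cells to both populations, although the sample titles speak of GFP negative and GFP positive mice. All values by mouse rest on the protocol and on 5 tags found in both lanes. High activity of the p21 promoter is often taken as a sign of senescence, and the comparison asks what sets such cells apart from the other cells of the same fat. After filtering, 9602 non-GFPhigh cells (754 to 2533 per mouse) and 9689 GFPhigh cells (1160 to 2602 per mouse) were kept. Summed over its cells, a mouse held 7618821 to 32778106 UMIs in the non-GFPhigh population, the lowest being mouse 4, and 15835321 to 40439398 UMIs in the GFPhigh population. The median mitochondrial share of a cell was 3.81% in non-GFPhigh and 4.35% in GFPhigh cells. By the protocol each population was a single droplet lane, so every difference below is also a difference between lanes.

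Macrophages dominated the GFPhigh population and were almost absent from the rest. They made up 54.65% of GFPhigh cells (exact 95% interval 53.7 to 55.6%) and 1.30% of non-GFPhigh cells (1.08 to 1.55%), a 49.7-fold higher share after allowing for mouse (log2 5.64 ± 0.48, adjusted p = 6.69e-12, higher in 5 of 5 mice). Across mice the GFPhigh share ran from 28.9 to 70.5% and the non-GFPhigh share from 0.301 to 2.13%. Neutrophils rose 4.35-fold (2.12 ± 0.50, adjusted p = 0.000320), from 0.594 to 5.21% of cells, with mouse 4 (15.5%) and mouse 5 (7.49%) well above the others (0.769 to 1.64%) in the GFPhigh population. Without mouse 4 the change was 1.82 ± 0.56 (adjusted p = 0.00323). Lymphatic endothelial cells rose 2.46-fold (1.30 ± 0.57, adjusted p = 0.0390), from 0.135% (0.0721 to 0.231%) to 0.310% (0.209 to 0.442%). Both moved in 5 of 5 mice. Lymphocytes were depleted. T cells fell from 14.1 to 0.991% of cells, 14.7-fold lower (-3.88 ± 0.49, adjusted p = 4.15e-08). B cells fell from 14.7 to 1.54%, 7.81-fold lower (-2.97 ± 0.45, adjusted p = 7.29e-07). Plasma cells fell from 3.78 to 0.495%, type 2 innate lymphoid cells from 1.78 to 0.175% and NK cells from 0.562 to 0.0310%, with adjusted p between 7.29e-07 and 1.46e-05.

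Among cells of the tissue framework, stromal cells fell from 36.4% (35.4 to 37.3%) to 16.04% (15.3 to 16.8%), 2.40-fold lower (-1.26 ± 0.39, adjusted p = 0.00426). Mesothelial cells, the lining of the fat pad, fell from 6.95 to 1.23% (-1.90 ± 0.46, adjusted p = 0.000410). Mural cells, which wrap small vessels, fell from 3.92 to 1.12% (-1.98 ± 0.43, adjusted p = 0.000117). All 11 classes called by edgeR's quasi-likelihood test moved the same way in 5 of 5 mice. Blood endothelial cells did not pass the test (9.14% against 8.11%, -0.36 ± 0.41, adjusted p = 0.421, higher in 2 of 5 mice). Neither did monocytes (2.51% against 5.00%, -0.07 ± 0.45, adjusted p = 0.871, higher in 2 of 5) or dendritic cells (1.37% against 0.929%, -0.59 ± 0.44, adjusted p = 0.216, higher in 2 of 5). Shares sum to a fixed total and are set by the gate. With macrophages left out of the total, the shares of stromal (-0.15 ± 0.40, adjusted p = 0.712), mesothelial (-0.72 ± 0.45, adjusted p = 0.136) and mural cells (-0.86 ± 0.44, adjusted p = 0.0820) no longer passed. Monocytes were then higher (1.04 ± 0.45, adjusted p = 0.0384). The other calls held at other sizes: T cells -2.77, B cells -1.80, plasma cells -1.91, type 2 innate lymphoid cells -2.18, NK cells -2.93, neutrophils 3.21 and lymphatic endothelial cells 2.43 (adjusted p 2.56e-07 to 0.000899). With tags called by ratio the stromal call was lost (-0.53 ± 0.34, adjusted p = 0.133), blood endothelial cells were lower (-0.84 ± 0.35, adjusted p = 0.0264) and T cells were at -2.92 (adjusted p = 1.76e-09). Without mouse 1 NK cells were at -4.77 (adjusted p = 1.68e-05). Without the block for mouse, the calls of stromal (-1.03, adjusted p = 0.114) and lymphatic endothelial cells (1.22, adjusted p = 0.0789) were lost and neutrophils were at 2.86 (adjusted p = 0.00747). Leaving out mouse 2, 3, 4 or 5 ended the lymphatic endothelial call (adjusted p 0.0618 to 0.1002). The exact sign-flip test over 5 mice, whose smallest possible p is 0.062, gave that value for each of the 11 classes (adjusted p = 0.0795). The gate was set on cells of wildtype mice.

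**Figure D1:**
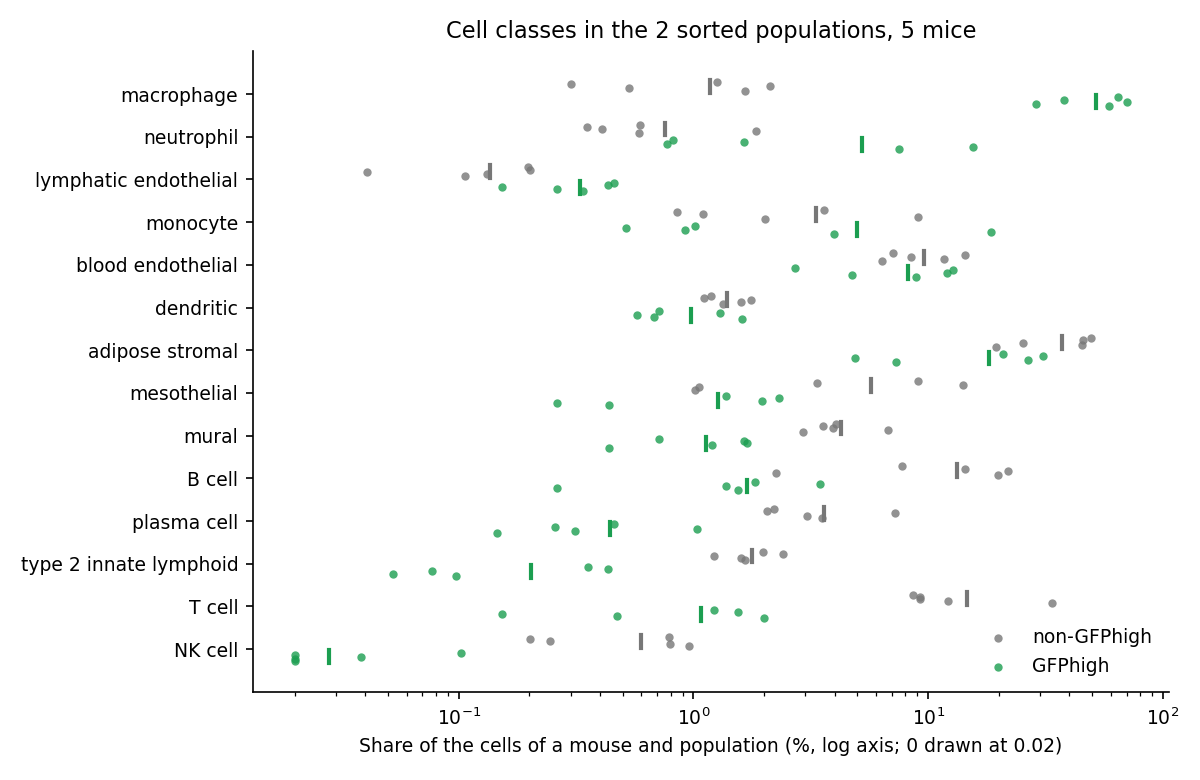
Share of each cell class among the cells of a mouse and population, in percent on a log axis (0 drawn at 0.02), with 1 point per mouse and vertical bars at the means of 5 non-GFPhigh (grey) and 5 GFPhigh (green) values. Macrophages lie between 28.9 and 70.5% in the GFPhigh population and between 0.301 and 2.13% in the other, while T cells, B cells, plasma cells, type 2 innate lymphoid cells and NK cells lie lower in GFPhigh cells of every mouse.

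Cdkn1a encodes p21, an inhibitor of cyclin-dependent kinases, and the sort reports its promoter. Over all cells it rose 1.902-fold in GFPhigh cells, from 78.7 ± 24.5 to 145 ± 25.8 CPM (log2 0.93 ± 0.21, adjusted p = 0.0120, higher in 5 of 5 mice). Its level differed more between cell classes than between populations. Without TMM scaling, endothelial cells held 577 ± 233 CPM in the non-GFPhigh and 645 ± 261 CPM in the GFPhigh population (5 mice). Monocytes held 204 ± 85.8 and 304 ± 89.7 CPM (4 mice), macrophages 214 ± 67.8 (3 mice) and 127 ± 20.8 CPM (5 mice). Stromal cells held 56.6 ± 13.97 and 62.7 ± 9.795 CPM (5 mice), and T cells 14.25 ± 6.68 CPM in the non-GFPhigh population (5 mice). The difference per mouse, 56.9 ± 38.4 CPM (mean ± SD, 5 mice), was made up of 69.6 ± 50.8 CPM from the changed makeup of classes and -12.8 ± 26.2 CPM from the level within classes. Only mouse 4 had a higher level within classes (31.9 CPM, beside 5.81 CPM from class makeup). The part of each class, macrophages included, was not separated. Non-GFPhigh macrophages numbered 6 in mouse 2 (281 CPM) and 4 in mouse 4 (0 CPM).

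Within classes, no rise of Cdkn1a passed the edgeR test. The log2 fold changes were 0.11 ± 0.10 in stromal cells (adjusted p = 0.508, higher in 4 of 5 mice) and 0.14 ± 0.06 in endothelial cells (adjusted p = 0.266, 4 of 5). They were 0.54 ± 0.16 in monocytes (adjusted p = 0.0641, 4 of 4), 0.55 ± 0.42 in B cells (adjusted p = 0.614, 2 of 4) and -0.43 ± 0.28 in mesothelial cells (adjusted p = 0.923, 1 of 3). In stromal cells the sign turned when each cell was thinned to 1000 UMIs (-0.23, adjusted p = 0.702) and with cluster as a term (-0.039, adjusted p = 0.882). It passed with tags called by ratio (0.26, adjusted p = 0.0384). The monocyte value passed with tags called by ratio (0.74, adjusted p = 0.0236), without a filter on low counts (0.57) and with at least 10 counts in every library (0.53, adjusted p = 0.0397). It was 0.12 ± 0.26 with cluster as a term (adjusted p = 0.977). In macrophages Cdkn1a fell 1.54-fold, from 213 ± 68.6 to 136 ± 24.0 CPM (-0.62 ± 0.14, adjusted p = 0.0297, lower in 3 of 3 mice). That call was lost without mouse 3 (-0.68, adjusted p = 0.140), without mouse 5 (-0.48, adjusted p = 0.153), with each cell thinned to 1000 UMIs (-0.36, adjusted p = 0.824) and without the block for mouse (-0.64, adjusted p = 0.239). The macrophages of the populations also lay in different clusters. Cluster 7, at 199.6 CPM of Cdkn1a, held 65 of 125 non-GFPhigh macrophages. Clusters 2 (68.01 CPM) and 9 (95.5 CPM) held 1655 and 780 GFPhigh cells and 1 non-GFPhigh cell each. Cluster as a term was not run for macrophages, so a different makeup and a lower level within clusters were not told apart.

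**Figure D2:**
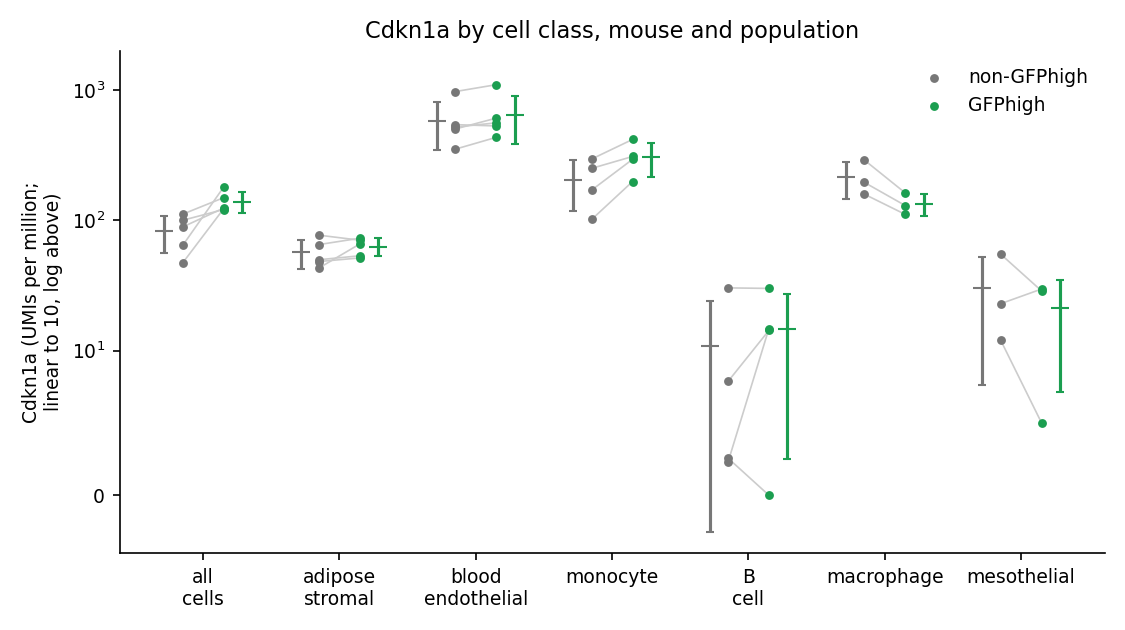
Cdkn1a in CPM of each summed library (linear to 10 and log above), with grey lines joining the non-GFPhigh (grey) and GFPhigh (green) value of a mouse and bars for mean ± SD of the mice tested (5 for all, stromal and endothelial cells, 4 for monocytes and B cells, 3 for macrophages and mesothelial cells). Endothelial cells hold the highest levels in both populations, and the 3 macrophage pairs all slope downwards.

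The share of cells with at least 1 Cdkn1a UMI was compared after thinning each cell to 1000 UMIs. No kept cell was shallower than that. The share over all cells was 7.29 ± 1.86% in non-GFPhigh and 11.2 ± 2.26% in GFPhigh cells (26.0 and 42.1% before thinning), higher in 5 of 5 mice with an exact sign-flip p of 0.062, the smallest that 5 mice allow (adjusted p = 0.438 over 7 comparisons). At 2000 UMIs it was higher in 4 of 5 mice (11.8 ± 3.49 and 18.5 ± 3.74%, exact p = 0.125). Endothelial cells had the highest thinned shares, 37.5 ± 9.73 and 40.7 ± 12.2% (exact p = 0.25, 79.0 and 84.2% before thinning). Monocytes had 12.8 ± 7.84 and 23.6 ± 4.77% (exact p = 0.25, 49.98 and 69.2%) and macrophages 14.6 ± 4.59 and 9.66 ± 3% (exact p = 0.5, 52.7 and 43.4%). Stromal cells had 4.70 ± 1.06 and 4.29 ± 1.57% (exact p = 0.812, 25.9 and 31.0% before thinning) and mesothelial cells 1.94 ± 2.22 and 1.31 ± 2.26% (exact p = 1, 13.7 and 16.3%). B cells, which served as the background, had 0.748 ± 1.20 and 0.694 ± 1.39% (exact p = 0.75, 6.06 and 12.99%), at a median of 7433 and 11369 UMIs per cell against 9996.5 and 12426 over all cells. With 3 or 4 mice the smallest possible exact p was 0.25 or 0.125, and none of these shares could be called different.

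Over all cells no list was tested. Genes named here that rose were of macrophages and those that fell of antibodies, beside the macrophage and plasma cell shares above. The C-type lectins Cd209f (log2 10.74 ± 0.24, adjusted p = 1.31e-05), Cd209g (10.61 ± 0.26, adjusted p = 1.33e-05) and Cd209b (9.73 ± 0.41, adjusted p = 4.66e-05) rose in 5 of 5 mice, Cd209f from 0.191 ± 0.173 to 348 ± 176 CPM. The immunoglobulin genes Ighv1-82 (-4.56 ± 0.70, adjusted p = 0.00253) and Igkv6-32 (-4.13 ± 0.74, adjusted p = 0.00463), whose close relatives can share reads, fell in 5 of 5 mice. So did Jchain, which joins immunoglobulin chains (-4.05 ± 0.65, adjusted p = 0.00294). In total 3843 genes were higher and 3590 lower of 15389 tested, and these counts mix the makeup of the populations with levels inside cells.

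Stromal cells, the fibroblast and progenitor class, differed between populations in genes of the extracellular matrix (list adjusted p = 3.95e-08, and adjusted p = 0.301 with an estimated correlation). Tenascin C (Tnc), a matrix glycoprotein of wounds, rose 10.0-fold (log2 3.32 ± 0.28, adjusted p = 0.000154), from 2.34 ± 2.25 to 24.5 ± 24.5 CPM. Periostin (Postn), a matrix protein of healing tissue, rose 2.08-fold (1.05 ± 0.11, adjusted p = 0.000589). Fibronectin (Fn1) rose 1.98-fold (0.98 ± 0.15, adjusted p = 0.00534) from 771.7 ± 192.5 to 1544 ± 393.1 CPM, and Mmp14, a membrane-bound collagenase, 1.63-fold (0.70 ± 0.12, adjusted p = 0.00940). The lipid transporter Abca8a fell 2.36-fold (-1.24 ± 0.16, adjusted p = 0.00237), from 374 ± 50.8 to 167 ± 70.2 CPM. The methyltransferase Inmt fell 2.34-fold (-1.22 ± 0.24, adjusted p = 0.0154) and Alkal2, a ligand of ALK receptors, 2.49-fold (-1.32 ± 0.18, adjusted p = 0.00291). The glutathione transferase Gsta3 (-1.20 ± 0.14, adjusted p = 0.00127) and the adhesion gene Adam23 (-1.30 ± 0.17, adjusted p = 0.00228) fell as well. Each of these genes moved the same way in 5 of 5 mice (3492 non-GFPhigh and 1554 GFPhigh cells). Cluster 1, with Inmt, Abca8a and Alkal2 among its leading genes, held 1498 non-GFPhigh and 324 GFPhigh cells. Cluster 16 (Saa3, Cxcl5) held 179 and 224, cluster 5 held 789 and 426 and cluster 6 held 771 and 408. With cluster as a term these genes still passed at smaller values, and Tnc was not tested. That fit took clusters of 1 mouse as separate (16 units from 5 mice) and can understate p. Alkal2 was at -0.57, Gsta3 at -0.49, Adam23 at -0.64, Inmt at -0.68 and Abca8a at -0.66. Fn1 was at 0.52 ± 0.11, Mmp14 at 0.55 and Postn, the least changed, at 0.93 ± 0.14.

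The largest rises among stromal cells were of macrophage genes, at low levels. The mannose receptor Mrc1 rose 96.4-fold (log2 6.59 ± 0.24, adjusted p = 5.30e-07), from 0.379 ± 0.361 to 48.6 ± 35.8 CPM, and the complement gene C1qa 45.7-fold (5.51 ± 0.40, adjusted p = 4.67e-05), from 2.2 ± 2.13 to 110 ± 57.9 CPM. The secreted Pf4 (6.04 ± 0.22), Retnla (5.96 ± 0.26), F13a1 (5.73 ± 0.44), Wfdc17 (5.63 ± 0.20), C1qc (5.53 ± 0.36) and Ccl6 (5.29 ± 0.36) rose in 5 of 5 mice with adjusted p between 5.30e-07 and 6.81e-05. As judged from 13 macrophage markers, RNA of macrophages made up 2.73 ± 1.58% of the UMIs of GFPhigh and 0.1996 ± 0.0925% of non-GFPhigh stromal cells (5 mice). Immunoglobulin genes, the products of plasma and B cells, fell: Igkc from 443 ± 22.4 to 101 ± 38.7 CPM (-2.18 ± 0.15, adjusted p = 3.86e-05), Ighm (-1.90 ± 0.12, adjusted p = 2.45e-05) and Jchain (-2.37 ± 0.12, adjusted p = 4.72e-06), beside plasma cell shares of 3.78% in the non-GFPhigh and 0.495% in the GFPhigh population.

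Lists of p53 targets, CDK inhibitors and proliferation genes were not called by camera in stromal cells. Of 27 measured p53 targets 2 rose and none fell (2 and 0 adjusted over the list alone). The stress cytokine Gdf15 rose 3.89-fold (1.96 ± 0.28, adjusted p = 0.00371, 5 of 5 mice) and the adenylate kinase Ak1 1.43-fold (0.51 ± 0.11, adjusted p = 0.0187, 5 of 5). Plk2 was at 0.57 ± 0.17 (adjusted p = 0.0715), and the list was not called by camera (adjusted p = 0.0593, and adjusted p = 0.357 with an estimated correlation) but was by fry (upwards, adjusted p = 0.0472). None of 6 CDK inhibitors passed (list adjusted p = 0.850, median -0.047 and mean 0.041). Cdkn2a, the source of p16 and Arf, was at 0.43 ± 0.19 (adjusted p = 0.193, higher in 3 of 5 mice) and Cdkn2b at 0.10 ± 0.18 (adjusted p = 0.770). Of 14 proliferation genes Stmn1 alone passed (0.55 ± 0.14, adjusted p = 0.0456, none adjusted over the list alone; list adjusted p = 0.850). Of 25 immediate early and heat shock genes 3 rose and 1 fell (4 and 2 adjusted over the list alone; list adjusted p = 0.623). Dusp1 (0.55 ± 0.11, adjusted p = 0.0160) and Ier3 (0.996 ± 0.19, adjusted p = 0.0161) rose in 5 of 5 mice, and Fosb fell in 4 of 5 (-0.39 ± 0.11, adjusted p = 0.0496).

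The 3 lists of secreted senescence factors were called higher in stromal cells. Of 24 SASP cytokines and chemokines 8 rose and 1 fell (12 and 2 adjusted over the list alone; camera adjusted p = 2.46e-13, and adjusted p = 0.0732 with an estimated correlation). Ccl8, a chemokine of resident macrophages, rose 17.5-fold (4.13 ± 0.10, adjusted p = 4.19e-08) and Ccl9 10.9-fold (3.44 ± 0.32, adjusted p = 0.000259). Ccl8 turned to -8.66 (adjusted p = 0.0111) when free RNA was subtracted. This list was no longer called after the macrophage profile (adjusted p = 0.0681) or free RNA (adjusted p = 0.833) was subtracted. Of 19 SASP proteases and inhibitors 9 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 7.13e-08, and adjusted p = 0.0925 with an estimated correlation). The risers included Mmp14 and the cathepsins Ctsb (0.60 ± 0.08, adjusted p = 0.00305) and Ctsd (0.62 ± 0.10, adjusted p = 0.00624). Of 22 SASP growth factors and binding proteins 4 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.00326, and adjusted p = 0.357 with an estimated correlation). Tgfb2, a fibrosis-related cytokine (0.69 ± 0.07, adjusted p = 0.000305), and Ccn1, a matrix-associated signalling protein (0.95 ± 0.16, adjusted p = 0.00748), rose in 5 of 5 mice, and the growth factor Hgf fell in 5 of 5 (-0.55 ± 0.12, adjusted p = 0.0228).

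Matrix and tissue lists of the stromal class were also called higher. Of 33 matrix genes 15 rose and 1 fell (20 and 3 adjusted over the list alone; camera adjusted p = 3.95e-08, and adjusted p = 0.301 with an estimated correlation). The risers ran from Fbn1 (0.40 ± 0.08) to Tnc, and the single gene that fell was Fbln1 (-0.37 ± 0.10, adjusted p = 0.0449). With cluster as a term Fbln1 (-0.11, adjusted p = 0.382), Eln (0.50 to 0.16, adjusted p = 0.513), Vcan (0.44 to 0.19, adjusted p = 0.280) and Col5a2 (0.58 to 0.33, adjusted p = 0.0611) lost their calls. Fbln1 (adjusted p = 0.0755) and Col5a2 (adjusted p = 0.0510) also lost them on subtraction of the macrophage profile. Of 21 TGF-beta and myofibroblast genes 5 rose (8 up and 1 down adjusted over the list alone; adjusted p = 0.00443, and adjusted p = 0.357 with an estimated correlation). They included the tropomyosin Tpm1 (0.48 ± 0.11, adjusted p = 0.0281) and Cthrc1, a gene of activated fibroblasts (1.20 ± 0.32, adjusted p = 0.0485), both higher in 4 of 5 mice. Of 13 interstitial progenitor genes 2 rose (5 adjusted over the list alone; adjusted p = 0.00334, and adjusted p = 0.449 with an estimated correlation), namely Fbn1 and Dact2 (0.57 ± 0.14, adjusted p = 0.0425, higher in 4 of 5 mice). Of 19 hypoxia and glycolysis genes 6 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.000631, and adjusted p = 0.383 with an estimated correlation). Examples were Pgk1 (0.59 ± 0.11, adjusted p = 0.0152) and Pkm (0.55 ± 0.12, adjusted p = 0.0262). Without the block for mouse the growth factor (adjusted p = 0.0642), progenitor (adjusted p = 0.163) and TGF-beta lists (adjusted p = 0.0540) were not called.

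Immune and lysosomal lists rose in stromal cells beside the macrophage RNA share of 2.73%. Of 14 resident macrophage genes (median log2 5.96) 10 rose (12 adjusted over the list alone; camera adjusted p = 3.42e-88, and adjusted p = 0.00645 with an estimated correlation). The scavenger receptor Cd163 rose from 1 to 403 UMIs, a ratio of 698 (124.5 to 27630). Of 8 MHC class II genes 7 rose (8 adjusted over the list alone; adjusted p = 1.46e-18, and adjusted p = 0.0732 with an estimated correlation). Of 17 lipid-associated macrophage genes 9 rose and 1 fell (11 and 1 over the list alone; 1.06e-09, and adjusted p = 0.0732 with an estimated correlation). Of 16 complement genes 7 rose (10; 4.04e-17, and adjusted p = 0.0732 with an estimated correlation). H2-Aa rose 4.49-fold (2.17 ± 0.24, adjusted p = 0.000682). Of 26 lysosomal genes 14 rose (18; 1.89e-10, and adjusted p = 0.301 with an estimated correlation). Of 19 NF-kB targets 8 rose (12; 1.04e-06, and adjusted p = 0.357 with an estimated correlation), such as Ccrl2 (1.31 ± 0.19). Of 32 interferon response genes 4 rose (12; 1.59e-05, and adjusted p = 0.449 with an estimated correlation), among them Irf7 (1.21 ± 0.28, adjusted p = 0.0307) and Isg15 (1.08 ± 0.29, adjusted p = 0.0479, 4 of 5 mice).

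By edgeR with mouse as a block, 692 genes were higher and 345 lower among 12039 tested in stromal cells, and 14 of 24 lists were called, all upwards (1 with an estimated correlation). After subtraction of the macrophage profile 574 genes passed (376 higher, 198 lower), Tnc (3.37 ± 0.29, adjusted p = 0.00159), Postn (1.10 ± 0.12, adjusted p = 0.00494) and Abca8a (-1.19 ± 0.16, adjusted p = 0.0107) among them. The MHC class II (adjusted p = 0.406) and resident macrophage lists (adjusted p = 0.626) were no longer called. The resident macrophage list also lost its call with free RNA subtracted (adjusted p = 0.669). Without mouse 3, 4 or 5 the count was 374, 414 or 395, and without the block for mouse 226. In simulated counts 17 of 188 calls were false.

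**Figure D3:**
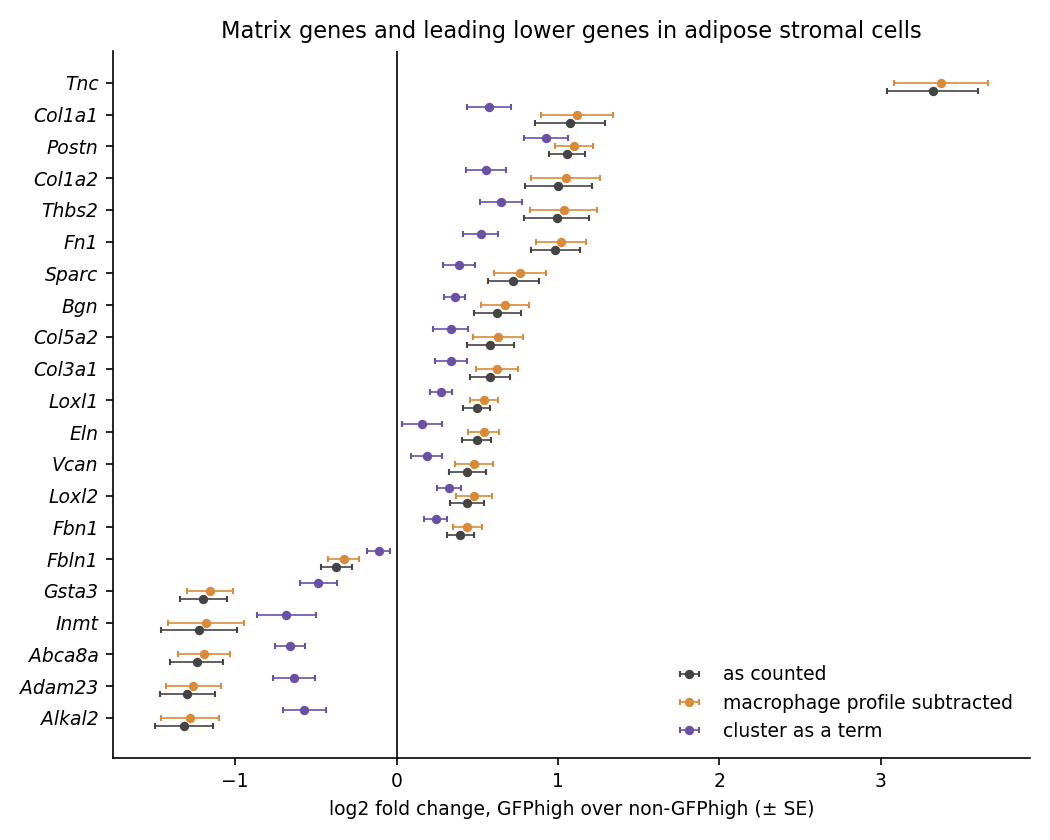
Log2 fold change (GFPhigh over non-GFPhigh, 5 mice, ± SE) of the 16 matrix genes past the threshold and of 5 genes lower in GFPhigh stromal cells, as counted, after subtraction of the macrophage profile and with cluster as a term (Tnc was not tested with that term). Subtraction leaves the values near those as counted, and the cluster term brings most of them closer to 0.

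In endothelial cells of blood vessels the gap junction gene Gja5, typical of arteries, fell 5.16-fold (log2 -2.37 ± 0.38, adjusted p = 6.04e-05), from 23.3 ± 8.50 to 4.25 ± 5.85 CPM. The basement membrane gene Nid2 fell 2.56-fold (-1.36 ± 0.27, adjusted p = 0.00114). Fth1, which stores iron, rose 1.58-fold (0.66 ± 0.06, adjusted p = 3.15e-10), from 1168 ± 175 to 1859 ± 408 CPM. The lipid carrier Apoe rose 1.93-fold (0.95 ± 0.07, adjusted p = 4.43e-11), from 1101 ± 177 to 2144 ± 459 CPM, beside 1328 CPM in free RNA of the non-GFPhigh and 9085 CPM in that of the GFPhigh lane. With free RNA subtracted it rose by 0.61 and still passed. All moved the same way in 5 of 5 mice (878 non-GFPhigh and 786 GFPhigh cells). After subtraction of the macrophage profile Gja5 (-2.30, adjusted p = 0.00188), Nid2 (-1.33, adjusted p = 0.014), Fth1 (0.39 ± 0.06, adjusted p = 0.000443) and Apoe (0.42 ± 0.08, adjusted p = 0.00820) still passed. Most cells of both populations lay in 1 cluster (701 non-GFPhigh and 655 GFPhigh cells).

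Within endothelial cells the largest rises among the named genes were of macrophage genes. Macrophage RNA was estimated there at 6.12 ± 2.28% of GFPhigh and 0.225 ± 0.133% of non-GFPhigh UMIs. The chemokine gene Ccl8 went from 3 to 1681 UMIs, a ratio of 529 (180.7 to 2568), and Ccl12 from 0 to 302 UMIs, at least 95.03-fold. Ratios were 210.5 (37.4 to 8352) for Cd163, 206 (36.55 to 8165) for Clec10a, and 179 (49.3 to 1486) for Retnla. They were 156 (27.6 to 6189) for Folr2, 120.4 (33.0 to 999) for Ms4a7 and 105 (35.55 to 511) for F13a1, each higher in 5 of 5 mice. Immunoglobulin genes and the protease inhibitor Slpi (-1.57 ± 0.18, adjusted p = 1.16e-07), all leading genes of plasma cell cluster 26, fell in 5 of 5 mice, with free RNA not excluded. Igkc changed by -2.48 ± 0.07 (adjusted p = 2.17e-21) and Igha by -2.65 ± 0.43 (adjusted p = 8.35e-05), with Jchain (-2.52 ± 0.22, adjusted p = 4.45e-10), Ighm (-1.995 ± 0.10, adjusted p = 6.81e-16) and Ighg1 (-1.65 ± 0.22, adjusted p = 3.91e-06).

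Lists of p53 targets, CDK inhibitors, proliferation genes and SASP growth factors were not called in endothelial cells. None of 20 p53 targets passed (camera adjusted p = 0.821; Btg2 0.17 ± 0.06, adjusted p = 0.136) and none of 4 CDK inhibitors (0.483; Cdkn1c -0.18 ± 0.13, adjusted p = 0.587). Nor did any of 12 proliferation genes (0.671; Pcna -0.18 ± 0.11, adjusted p = 0.523) or of 13 SASP growth factors (0.813; 2 up and 1 down adjusted over the list alone; Igf1 0.65 ± 0.20, adjusted p = 0.0679). Of 23 immediate early genes 2 rose (4 up and 2 down adjusted over the list alone; list adjusted p = 0.182), Fos (0.50 ± 0.08, adjusted p = 5.90e-05) and Atf3 (0.60 ± 0.12, adjusted p = 0.00163). Of 16 SASP cytokines 8 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 1.84e-36), such as Cxcl2 (4.41 ± 0.22) and Ccl6 (4.16 ± 0.34). Of 11 SASP proteases and inhibitors 3 rose (4 up and 1 down adjusted over the list alone; adjusted p = 0.00777, and adjusted p = 0.102 with an estimated correlation), namely Ctsb (1.13 ± 0.10), Ctsd (0.65 ± 0.09) and Timp2 (0.86 ± 0.17). Both SASP lists lost their call on subtraction of the macrophage profile (adjusted p = 0.634 and 0.948).

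The other called lists of endothelial cells were higher beside the macrophage RNA share of 6.12%. All 6 MHC class II genes rose (adjusted p = 5.24e-98), 11 of 13 resident macrophage genes (13 adjusted over the list alone; 1.14e-68), 6 of 13 complement genes (7; 7.72e-58) and 12 of 26 lysosomal genes (15; 2.48e-16). H2-Aa was at 3.64 ± 0.15, Pf4 at 4.99 ± 0.23, C1qb at 5.52 ± 0.16 and Ctsc at 4.21 ± 0.22. These 4 lists were no longer called after subtraction of the macrophage profile (adjusted p 0.352, 0.874, 0.404 and 0.354). Of 12 lipid-associated macrophage genes 6 rose (7 up and 1 down adjusted over the list alone; 1.5e-11, after subtraction 0.0408), including Lgals3 (1.95 ± 0.16). Of 17 NRF2 targets, which answer oxidative stress, 5 rose (6; 1.01e-05, and adjusted p = 0.0804 with an estimated correlation; after subtraction 0.00333). Ftl1 (0.84 ± 0.07), Fth1 and Hmox1 (0.998 ± 0.16) were among them. Of 31 interferon response genes 3 rose (6; 0.0264, and adjusted p = 0.292 with an estimated correlation), Ifi27l2a (1.09 ± 0.13), Isg15 (0.47 ± 0.11) and Ifitm3 (0.24 ± 0.06). Of 15 NF-kB targets 2 rose (5; 0.0499, and adjusted p = 0.316 with an estimated correlation), Nfkbiz (0.52 ± 0.11) and Nfkbia (0.28 ± 0.07). Without the block for mouse the interferon (adjusted p = 0.0534) and NF-kB lists (adjusted p = 0.0949) were not called, and the NF-kB call was also lost on subtraction of the macrophage profile (0.634). With free RNA subtracted the SASP protease (adjusted p = 0.270) and NF-kB lists (adjusted p = 0.119) lost their call. After subtraction of the macrophage profile, proliferation genes were called lower (adjusted p = 0.0135) and adipogenic genes higher (adjusted p = 0.00755). With an estimated correlation no list passed after that subtraction, the lipid-associated and NRF2 lists included (adjusted p 0.202 or more).

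In endothelial cells 236 genes were higher and 67 lower among 8481 tested, and 10 of 24 lists were called (6 with an estimated correlation). With the macrophage profile subtracted 36 genes remained (12 higher, 24 lower), with free RNA subtracted 101, without mouse 3 173, with each cell thinned 31 and without the block for mouse 132.

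**Figure D4:**
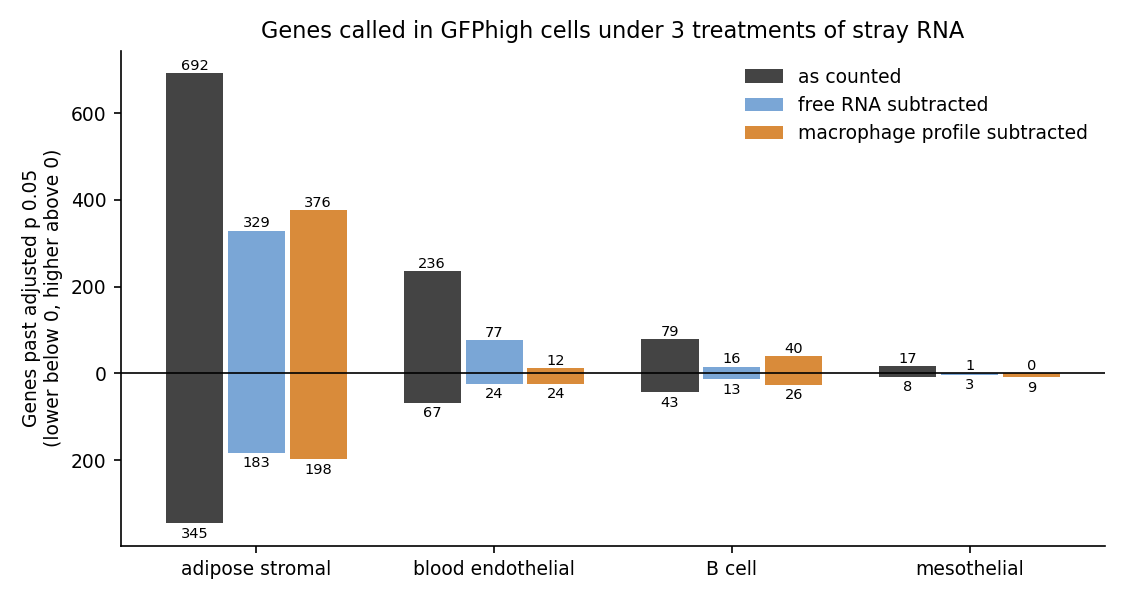
Genes called higher (upwards) and lower (downwards) in GFPhigh stromal, endothelial, B and mesothelial cells (5, 5, 4 and 3 mice), as counted, with free RNA subtracted and with the macrophage profile subtracted. Endothelial calls go from 303 as counted to 36 after the macrophage profile is subtracted, while stromal calls go from 1037 to 574; the mesothelial subtraction rests on a share raised by Trem2.

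Stromal and endothelial cells were compared for the size of their changes in the same 5 mice. The cytokine gene Tgfb2 changed by a log2 of 0.68 in stromal and -1.45 in endothelial cells (difference 2.13 ± 0.36, adjusted p = 0.00513). Ccl8 changed more in endothelial cells (4.12 against 8.92, difference -4.79 ± 0.45, adjusted p = 1.49e-05), as did the lysosomal Ctsc (1.48 against 4.22, -2.73 ± 0.35, adjusted p = 0.000521) and the ferritin gene Ftl1 (0.05 against 0.82, -0.77 ± 0.12, adjusted p = 0.00243), beside macrophage RNA shares of 2.73 and 6.12%. Endothelial Ccl8 started from 3 UMIs, and that low level may set its difference. Cdkn1a did not differ (-0.02 ± 0.12, adjusted p = 0.997). By the interaction term 291 of 11726 genes differed (121 more positive in stromal, 170 in endothelial cells), and 51, 89 or 108 without mouse 3, 4 or 5.

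GFPhigh monocytes carried more transcripts known from macrophages. Macrophage RNA was not estimated in this class, so a stray source is not excluded. Gpnmb, a glycoprotein of lipid-loaded macrophages, rose 36.6-fold (log2 5.19 ± 0.47, adjusted p = 6.48e-05), from 2.77 ± 3.25 to 138 ± 74.0 CPM. Fabp5, a fatty acid carrier, rose 7.31-fold (2.87 ± 0.17, adjusted p = 7.69e-06), from 111 ± 43.2 to 834 ± 376 CPM, and Ctsd, a lysosomal protease, 5.52-fold (2.46 ± 0.21, adjusted p = 4.79e-05). The chemokine genes Ccl7 (4.42 ± 0.30, adjusted p = 1.37e-05) and Ccl8 (0 against 749 UMIs, at least 81-fold) rose. So did Pf4 (1 against 540 UMIs, ratio 175, 31.3 to 6932), Ms4a7 (3.90 ± 0.36), the efferocytosis receptor Mertk (3.25 ± 0.59), the antiviral Rsad2 (3.17 ± 0.535) and Basp1 (3.15 ± 0.31). The transcription factors Ets1 (-1.98 ± 0.28, adjusted p = 0.00176) and E2f2 (-1.85 ± 0.34, adjusted p = 0.00802) fell, as did Pdlim1 (-1.81 ± 0.37), Fbxl20 (-1.78 ± 0.34) and Lrrk2 (-1.76 ± 0.39). All moved the same way in 4 of 4 mice (224 non-GFPhigh and 478 GFPhigh cells). The immunoglobulin genes Jchain (-3.04 ± 0.36), Igkc (-2.71 ± 0.21) and Ighm (-2.42 ± 0.17) fell, with free RNA not excluded. Most non-GFPhigh monocytes (178) lay in cluster 23, led by Ear2 and Adgre4. Most GFPhigh ones (382) lay in cluster 14, led by Chil3 and Ly6c2 (75.1% of its cells from mouse 4).

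Among monocyte lists, 3 of 11 p53 targets rose (3 adjusted over the list alone), without a call of the list (camera adjusted p = 0.146). They were Bax (0.74 ± 0.17, adjusted p = 0.0226), Plk2 (1.27 ± 0.34, adjusted p = 0.0413) and Rap2b (1.01 ± 0.24, adjusted p = 0.0271, 3 of 4 mice). Of 18 SASP cytokines 10 rose (11 up and 1 down adjusted over the list alone; 3.97e-14, and adjusted p = 0.0744 with an estimated correlation), such as Mif (1.64 ± 0.20) and Ccl2 (2.40 ± 0.43). Of 10 SASP proteases 6 rose and 1 fell (the same alone; 3.93e-06, and adjusted p = 0.162 with an estimated correlation), such as Ctsb (1.25 ± 0.18) and Ctsl (1.66 ± 0.26). SASP growth factors were not called (5 genes, adjusted p = 0.935, median -0.19 and mean 0.17; Vegfa alone rose, 1.97 ± 0.45). Neither were proliferation genes (5, 0.876; none passed, 1 up and 1 down over the list alone; Pcna 0.41 ± 0.19, adjusted p = 0.228) or immediate early genes (23, 0.423). Among the last, Ier3 rose (1.70 ± 0.22) and Jund (-0.79 ± 0.19) and Nr4a1 (-0.77 ± 0.19) fell, the same 1 and 2 adjusted over the list alone.

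Lists of lipid-associated macrophage genes and of stress genes were called higher in monocytes. Of 17 lipid-associated macrophage genes 13 rose (15 adjusted over the list alone; 3.41e-24, and adjusted p = 0.162 with an estimated correlation), including Spp1 (5.05 ± 0.40) and Cd63 (3.13 ± 0.37). Of 13 NRF2 targets 7 rose (9 up and 2 down; 1.23e-06, and adjusted p = 0.293 with an estimated correlation), such as Fth1 (1.75 ± 0.17) and Slc7a11 (1.56 ± 0.30). Of 24 lysosomal genes 13 rose (16; 9.89e-14, and adjusted p = 0.227 with an estimated correlation), such as Grn (1.34 ± 0.18). Of 16 hypoxia and glycolysis genes 8 rose (9; 6.49e-06, and adjusted p = 0.350 with an estimated correlation), such as Gapdh (0.76 ± 0.13). Of 15 unfolded protein genes 7 rose (10; 3.32e-05, and adjusted p = 0.162 with an estimated correlation), such as Hspa5 (0.73 ± 0.11). Of 30 interferon response genes 7 rose (17; 3.76e-07, and adjusted p = 0.546 with an estimated correlation), such as Isg15 (1.52 ± 0.33) and Ifit2 (2.58 ± 0.58), both in 3 of 4 mice. Complement genes were also called (6 of 9 rose, 7 up and 1 down over the list alone; 3.76e-07, and adjusted p = 0.216 with an estimated correlation; C1qa 2.69 ± 0.44). So were resident macrophage genes (2 of 5, the same alone; 0.000450, and adjusted p = 0.293 with an estimated correlation; Maf 0.87 ± 0.20). The test gave 260 genes higher and 144 lower of 5290. With cluster as a term 44 passed, with 1 mouse left out 72 to 609, and without the block for mouse 29.

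In B cells the chemokine gene Ccl8 (log2 7.08 ± 0.35, adjusted p = 9.79e-13), C1qa (6.08 ± 0.36, adjusted p = 2.00e-11) and Pf4 (3 against 61 UMIs, ratio 154, 50.2 to 766) rose in 4 of 4 mice. All are genes of macrophages, beside macrophage RNA shares of 1.52 ± 0.30% in GFPhigh and 0.211 ± 0.0654% in non-GFPhigh cells. The protease inhibitor Slpi (-2.44 ± 0.35, adjusted p = 0.000130), the antibody gene Ighg1 (-2.41 ± 0.39, adjusted p = 0.000825) and Icosl, a ligand for T cells (-1.84 ± 0.37, adjusted p = 0.00787), fell in 4 of 4 mice (1393 non-GFPhigh and 144 GFPhigh cells), with free RNA not excluded. Called lists were SASP cytokines (7 genes, 3 rose and 1 fell, 4 and 2 over the list alone; 4.36e-18; Cxcl2 4.93 ± 0.53) and resident macrophage genes (4, 3 rose, the same alone; 5.93e-20; Mrc1 2.15 ± 0.36). So were complement (8, 3 rose, 4 and 2 alone; 5.93e-20; C1qb 5.75 ± 0.37) and lipid-associated macrophage genes (12, 5 rose, 7 and 1 alone; 1.71e-09; Cd63 2.17 ± 0.31). Not called with an estimated correlation were SASP proteases (8, 2 rose, the same alone; 2.54e-05, and adjusted p = 0.214 with an estimated correlation; Ctsd 1.496 ± 0.19) and lysosomal genes (25, 4 rose, 8 and 1 alone; 8.94e-07, and adjusted p = 0.0976 with an estimated correlation; Grn 0.88 ± 0.17). The same held for NRF2 targets (12, 2 rose, the same alone; 0.00522, and adjusted p = 0.270 with an estimated correlation; Fth1 0.42 ± 0.09). It held for unfolded protein genes (17, 1 rose, 3 alone; 0.0225, and adjusted p = 0.607 with an estimated correlation; Xbp1 0.82 ± 0.21, higher in 2 of 4 mice) and immediate early genes (22, 1 rose, 2 alone; 0.025, and adjusted p = 0.565 with an estimated correlation; Egr1 0.83 ± 0.13). Among SASP cytokines Ccl5 fell from 256 to 2 UMIs, 16.9-fold lower (4.64 to 140.5). With an estimated correlation 4 lists were called with all mice, and none when any 1 mouse was left out or free RNA or the macrophage profile was subtracted. In all 79 genes were higher and 43 lower of 7978. With the macrophage profile subtracted 66 passed, and the SASP cytokine (0.0957), complement (0.170) and immediate early lists (0.454) lost their call. The count was 29 with free RNA subtracted, 66 without mouse 3, 63 without mouse 5 and 9 without the block for mouse, where the immediate early (0.353) and unfolded protein lists (0.0746) were not called.

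GFPhigh macrophages carried more of the genes of resident macrophages than the few non-GFPhigh macrophages. The scavenger receptor Marco (0 against 5449 UMIs, at least 50.4-fold), the lectin Cd209e (0 against 1358 UMIs, at least 12.6-fold) and the iron exporter Slc40a1 (3 against 8583 UMIs, ratio 79.45, 27.2 to 385) were higher in GFPhigh cells. The genes Ly6c2 (log2 -3.79 ± 0.48, adjusted p = 0.00153) and Plac8 (-3.73 ± 0.19, adjusted p = 1.10e-05) and the leukotriene receptor Ltb4r1 (-4.87 ± 0.80, adjusted p = 0.00639) fell, all in 3 of 3 mice. These rest on 115 non-GFPhigh and 4302 GFPhigh cells. Cluster 7, led by Fabp5, Cx3cr1 and Ccr2, held 65 non-GFPhigh cells, and clusters 2 (Cd209f, Ccl8) and 9 (Retnla, Lyve1) held 1655 and 780 GFPhigh cells and 1 non-GFPhigh cell each.

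Of 16 resident macrophage genes 15 rose in macrophages (16 adjusted over the list alone; 4.07e-85, and adjusted p = 0.293 with an estimated correlation), with the selenium carrier Selenop up 4.39-fold (2.13 ± 0.11) from 935 ± 306 to 4025 ± 899 CPM. Of 25 immediate early genes 13 rose (16 up and 1 down; 1.37e-07, and adjusted p = 0.665 with an estimated correlation; Egr1 1.16 ± 0.16). Of 19 SASP growth factors 5 rose (5; 0.00242, and adjusted p = 0.665 with an estimated correlation; Igf1 1.88 ± 0.17, Gas6 3.18 ± 0.28). Of 17 complement genes 8 rose and 1 fell (9 and 1; 1.63e-09, and adjusted p = 0.665 with an estimated correlation; C1qa 0.96 ± 0.08). Of 26 lysosomal genes 10 rose (16 and 1; 3.02e-06, and adjusted p = 0.674 with an estimated correlation; Ctsb 1.08 ± 0.16). Called lower were glycolysis genes (7 of 19 fell, 10 alone; 6.02e-08, and adjusted p = 0.293 with an estimated correlation; Pgk1 -0.81 ± 0.14) and matrix genes (3 of 32, 3 alone; 0.000140, and adjusted p = 0.702 with an estimated correlation; Fn1 -2.81 ± 0.30). So were proliferation genes (2 of 32, 2 alone; 0.00619, and adjusted p = 0.788 with an estimated correlation; Lmnb1 -1.37 ± 0.30) and MHC class II genes (2 of 12 fell and 1 rose, 8 and 1 alone; 0.00674, and adjusted p = 0.665 with an estimated correlation; Ciita -0.59 ± 0.15, Cd86 0.70 ± 0.15). In all 500 genes were higher and 245 lower of 11869. In simulated counts 22 of 94 calls were false. The count was 253 without mouse 3 and 146 without the block for mouse.

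In mesothelial cells, macrophage genes were higher as counted and immunoglobulin genes were lower. Ccl8 (log2 7.31 ± 0.32, adjusted p = 3.09e-14), C1qa (6.52 ± 0.43, adjusted p = 6.40e-11) and C1qc (0 against 38 UMIs, at least 73.75-fold) rose in 3 of 3 mice. No macrophage RNA share is given for this class, because its GFPhigh cells held the marker Trem2 at 230.3 CPM against 267.7 CPM in macrophages, and C1qc at 25.0 against 2808 CPM. Ighm fell 32.6-fold (-5.03 ± 0.46, adjusted p = 5.90e-08), from 2029 ± 3198 to 33.8 ± 1.87 CPM, and Igkc (-4.26 ± 0.44) and Jchain (-3.97 ± 0.42) fell in 3 of 3 mice, with free RNA not excluded (640 non-GFPhigh and 105 GFPhigh cells). Lists with members past the threshold were SASP cytokines (3 of 11 rose, 3 up and 1 down alone; 1.27e-23, and adjusted p = 0.286 with an estimated correlation) and complement genes (3 of 13, 4 and 1 alone; 9.63e-16, and adjusted p = 0.400 with an estimated correlation; median -0.068, mean 1.6) and resident macrophage genes (2 of 6, 2 and 2 alone; 1.21e-05, and adjusted p = 0.408 with an estimated correlation; Mrc1 3.52 ± 0.53). MHC class II (7 genes, 5 up alone; 5.62e-08, and adjusted p = 0.408 with an estimated correlation; H2-Aa 0.49 ± 0.12, adjusted p = 0.0871) and NF-kB genes (14, 1 alone; 0.00936, and adjusted p = 0.451 with an estimated correlation; Nfkbia 0.64 ± 0.15, adjusted p = 0.0848) were called higher with no member past the threshold. So were immediate early (23, 6 alone; 0.0129, and adjusted p = 0.458 with an estimated correlation; Fos 1.19 ± 0.36, adjusted p = 0.369) and progenitor genes (6, 2 alone; 0.0129, and adjusted p = 0.480 with an estimated correlation; Cd55 0.75 ± 0.22, adjusted p = 0.307). Unfolded protein (18, none alone; 0.0129, and adjusted p = 0.408 with an estimated correlation; Hspa5 -0.19 ± 0.08, adjusted p = 0.754) and TGF-beta genes (15, none alone; 0.0183, and adjusted p = 0.408 with an estimated correlation; Ltbp2 -0.60 ± 0.23, adjusted p = 0.693) were called lower. In all 17 genes were higher and 8 lower of 8328. None of the 17 kept its call with free RNA subtracted (1 gene higher, 3 lower), with each cell thinned (0 higher, 5 lower) or with the macrophage profile subtracted (0 higher, 9 lower, from a share raised by Trem2). Without mouse 2 the count was 55. Without the block for mouse 16 genes and 5 lists passed.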

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

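Tests of macrophage RNA in other classes and of the macrophage gate were chosen only after their results were seen. The tests on the stromal matrix genes were added after the calls were seen, on genes picked from those calls, and only their limits were written before they were run. Those on other splits of the samples were written before.

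In 7 of 58 groups of libraries, 1 mouse stood apart from the others by a gap test at the 95% level, and chance alone gives about 1 in 20 groups. Mouse 5 had 33.78% T cells in the non-GFPhigh population (others 8.61 to 12.2%) and the highest epithelial shares, 0.778% of GFPhigh (others 0 to 0.172%) and 0.107% of non-GFPhigh cells (others 0). Mouse 4 had 18.46% monocytes in the GFPhigh population (others 0.517 to 3.99%) and 1.86% neutrophils in the non-GFPhigh population (others 0.352 to 0.592%). Mouse 3 had 7.23% plasma cells in the non-GFPhigh population (others 2.06 to 3.52%). Mouse 1 had 1098 CPM of Cdkn1a in GFPhigh endothelial cells (others 433 to 608 CPM) and also the highest level in its non-GFPhigh endothelial cells, 972 CPM. The change of 291 genes differed between stromal and endothelial cells by an interaction term. A multiplexing tag not assigned to a mouse, CMO303, carried 390 UMIs in the non-GFPhigh and 674 UMIs in the GFPhigh lane, above the 3 that a count of 0 allows.

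Macrophage genes rose in GFPhigh cells of every other class tested, which may come from other cells (not examined in monocytes). The candidate source was tested with 13 macrophage markers, of which C1qa, C1qb and C1qc also stand in the complement list, Mrc1, Cd163 and F13a1 in the resident macrophage list and Trem2 in the lipid-associated list. Free RNA spread evenly over cells is argued against as the whole cause, since the 5% of cells with most marker UMIs held 48.47% of them in stromal cells (14.06% in an even spread) and 72.65% in endothelial cells (16.62%), although the ratio of free-RNA shares by macrophage and by other markers was 1.066 in stromal cells (2.688 in endothelial). Macrophages in doublets or fragments would give such a concentration (3.447 and 4.372 times an even spread) in these classes. In B cells it was 1.889 times, short of the 2 set for this cause, and in mesothelial cells 1.427 times, where Trem2 gave 396 of 828 marker UMIs, so no source is named for either. Outside the top cells the free-RNA ratios were 0.657 ± 0.0872 and 0.915 ± 0.214, which decides nothing, since removing the cells with most of these markers can only lower the ratio, so the source there stays open. Own transcription is argued against only in the top endothelial cells and cannot be told apart in the others or in stromal cells. Pooled endothelial markers, mostly from the top cells, kept macrophage proportions (SD of log2 ratios 0.2593, upper limit 0.428, stromal 0.5046 and 0.833).

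Macrophages were 54.65% of GFPhigh and 1.30% of non-GFPhigh cells. A gate that followed the Cdkn1a mRNA of each class is argued against, because the log2 share ratio of macrophages lay 5.993 ± 0.6281 above that of blood endothelial cells, whose Cdkn1a level was higher (645 against 127 CPM in the GFPhigh population). Fluorescence of macrophages other than GFP may have carried them over the gate. Cdkn1a being lower in GFPhigh than in non-GFPhigh macrophages would go with this (-0.6207 ± 0.1398, 3 mice). That call was lost without mouse 3 or 5, with cells thinned and without the block. A different makeup of macrophages can give the lower Cdkn1a too, as cluster 7 (199.6 CPM) held 65 of 125 non-GFPhigh macrophages and cluster 2 (68.01 CPM) 1655 GFPhigh cells and 1 non-GFPhigh cell. The gate was set on wildtype cells, whose fluorescence was not measured here. GFP that outlasts its mRNA and p21 activity earlier in the life of a macrophage stay open and were not tested.

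In GFPhigh stromal cells matrix genes were higher and Abca8a, Inmt, Alkal2, Adam23 and Gsta3 lower. RNA of macrophages is argued against, since 90.48% of these 21 genes (19) kept sign and call after its profile was subtracted, Col5a2 (0.58 ± 0.15 before, 0.63 ± 0.15 after, adjusted p = 0.0510) and Fbln1 (-0.37 ± 0.10 before, -0.33 ± 0.09 after, adjusted p = 0.0755) being the exceptions, with folds within their error and a smaller number of calls over all genes. With cluster as a term the log2 fold changes were 0.5116 times those without it (median of 20 genes, interval 0.488 to 0.613). Of the 20, 16 passed, in a fit that can understate p. A different makeup of stromal clusters and a change within clusters cannot be told apart, because clusters were drawn from the same genes. The activity of the p21 promoter, which defines the groups, stays open, as does the lane.

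With 4 to 16 splits that part the libraries of every mouse, the share of splits as large cannot fall under 0.05, so these counts decide nothing about chance. The real count, the highest of the other splits and the number of splits as large (the real split included) were 7433, 0 and 1 for genes of all cells, 1037, 0 and 1 in stromal cells, 303, 4 and 1 in endothelial cells, 404, 2 and 1 in monocytes, 122, 0 and 1 in B cells, 745, 0 and 1 in macrophages, 25, 1 and 1 in mesothelial cells, 11, 0 and 1 for class shares and 291, 0 and 1 for the interaction. For lists they were 14, 17 and 4 in stromal cells, 10, 11 and 4 in endothelial cells, 10, 12 and 2 in monocytes, 9, 10 and 2 in B cells, 9, 7 and 1 in macrophages and 9, 5 and 1 in mesothelial cells. Splits that keep some mice whole within a group gave up to 1811 stromal genes (2 of 84 drawn were as large as the real split). In endothelial cells they gave up to 122 and in monocytes 207, for reasons not tested.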

How the results depend on the processing

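Subtraction of the macrophage profile and cluster as a term were added only after the results were seen, and the other alternatives were set before.

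Libraries are few (3 to 5 mice per class), and each population is 1 lane by the protocol. The number of genes called within classes moved with many settings. Over all cells 5727 to 7829 genes were called, and Cdkn1a lay between 0.59 and 1.02. Cells kept ran from 17856 to 24620 beside 19291. Of the values of named genes under the alternatives 5020 stayed, 516 were weaker, 95 stronger and 34 had the other sign, and of those of class shares 148, 10, 1 and 7. Weaker values of named genes came most often from leaving out the block (134) and from leaving out mouse 3 (55) or mouse 5 (51). A limit of at least 50 cells per mouse and population gave no value for monocytes, B cells, macrophages and mesothelial cells. The cause of these moves was not tested.

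Genes called (as reported 1037 in stromal, 303 in endothelial, 404 in monocyte, 122 in B, 745 in macrophage and 25 in mesothelial cells) were, without a filter, 1815 stromal, 528 endothelial, 760 monocyte, 253 B, 1181 macrophage and 73 mesothelial. With at least 10 counts in every library they were 154 endothelial, 80 B and 7 mesothelial (5 B cell lists). The Wald test of DESeq2 called 156 endothelial, 233 monocyte and 49 B. With free RNA subtracted they were 512 stromal, 101 endothelial, 29 B and 4 mesothelial (5 B cell lists). With the macrophage profile subtracted they were 574 stromal, 36 endothelial (5 lists), 66 B and 9 mesothelial, the last from a share raised by Trem2. Cluster as a term gave 574 stromal, 123 endothelial and 44 monocyte. Each cell thinned to 1000 UMIs gave 182 stromal, 31 endothelial, 55 monocyte, 9 B (2 lists), 251 macrophage and 5 mesothelial (0 lists). Tags called by ratio gave 460 endothelial, 621 monocyte and 1280 macrophage. In B cells 77 were called with at least 2000 UMIs and 1000 genes and 70 at a mitochondrial limit of 20%, and 52 mesothelial with Scrublet doublets kept.

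Without the block for mouse 226 stromal, 132 endothelial, 29 monocyte, 9 B, 146 macrophage and 16 mesothelial genes (5 mesothelial lists) were called, 5727 genes over all cells and 9 class shares. With an estimated correlation 1 stromal, 6 endothelial, 0 monocyte, 4 B, 0 macrophage and 0 mesothelial lists were called, in place of 14, 10, 10, 9, 9 and 9. These calls were less firm: B cells had 0 without any 1 mouse and with free RNA or the macrophage profile subtracted, stromal cells 0 without mouse 3 and after either subtraction, and endothelial cells 4 or 5 with 1 mouse left out, 2 with free RNA and 0 with the macrophage profile subtracted. By the exact sign-flip test 0 of the 11 class shares passed.

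Leaving out 1 mouse at a time gave 5786 to 7123 genes over all cells (Cdkn1a 0.76 to 1.02), 374 to 1180 in stromal cells (13 to 15 lists), 173 to 307 in endothelial cells (8 to 10 lists), 72 to 609 in monocytes (10 to 11 lists), 63 to 119 in B cells (8 to 9 lists), 253 to 996 in macrophages (8 to 10 lists), 29 to 55 in mesothelial cells (6 to 9 lists), 10 class shares each time and 51 to 236 genes for the interaction. The lowest counts came without mouse 3 in stromal (374), endothelial (173) and macrophage libraries (253) and for the interaction (51). They came without mouse 5 in monocytes (72, then 117 without mouse 4, 258 without mouse 3, 609 without mouse 1) and B cells (63, then 66 without mouse 3). In mesothelial cells the count was 55 without mouse 2.

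Signs turned as follows, at adjusted p above 0.05 except where given. Stromal Ccl8 was -8.66 with free RNA subtracted (adjusted p = 0.0111, positive under the other settings run). That step cuts off counts that would turn negative, so this value can come from too much being removed. Stromal Cdkn1a was -0.23 with cells thinned and -0.039 with cluster as a term. Stromal Cdkn2b was -0.10 to 0.20 with 1 mouse left out (negative without mouse 5), -0.032 with tags by ratio and -0.015 with doublets kept. Endothelial Cdkn1b was -0.0032 with at least 10 counts, -0.097 to 0.075 with 1 mouse left out (negative without mouse 2), -0.028 with at least 2000 UMIs, -0.0022 with at least 500 UMIs, -0.0019 with tags by ratio, -0.039 with doublets kept and -0.20 with cells thinned. Thinning also turned endothelial Fas (-0.013) and Pcna (0.25), monocyte Hmgb2 (0.032) and H2afz (0.056), B cell Fos (-0.42) and Txn1 (-0.45), macrophage Cd86 (-0.012) and H2-DMa (0.12), and mesothelial H2-Ab1 (-0.056) and Anxa3 (0.58). Subtraction of free RNA turned Timp2 in endothelial (-0.072) and B cells (-0.096), and subtraction of the macrophage profile turned it too (-0.43 and -0.049), with endothelial Igf1 (-0.36) and Vcam1 (-0.13). Monocyte F13a1 was 0.37 with tags by ratio. In mesothelial cells with 1 mouse left out Cdkn1a ran from -1.04 to 0.049, Fos from -0.16 to 2.12 and Acta2 from -0.41 to 0.017, turning without mouse 1, and Anxa3 from -0.26 to 0.081, turning without mouse 3.

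The monocyte share turned to 0.61 without the block, -0.42 to 0.37 with 1 mouse left out (positive without mouse 1, 0.37, or mouse 2, 0.051), 0.057 with tags by ratio and 1.04 with the largest class left out (adjusted p = 0.0384), where blood endothelial cells turned to 0.76 and dendritic cells to 0.55. The difference in the share of cells with a Cdkn1a UMI turned, in percentage points, to 6.93 in B, 5.12 in stromal and 2.66 in mesothelial cells without thinning, and to 3.11, 0.255 and 0.855 at 2000 UMIs. Over all cells it was 6.76 at 2000 UMIs, higher in 4 of 5 mice (exact p = 0.125).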

Other observations

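The genes and clusters below were chosen only after the results were seen, and no test was planned for them.

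Beyond Gja5, Sema3g was lower in GFPhigh endothelial cells after subtraction of the macrophage profile (log2 -0.45, adjusted p = 0.00954), with Meis2 (-1.18) and Fbln5 (-0.49). Endothelial cluster 24, led by Rbp7, Sema3g and Efnb2, held 161 of 878 non-GFPhigh and 118 of 786 GFPhigh endothelial cells, and no list of arterial genes was tested. These genes were picked after their values were seen. Gja5 ran from -3.25 to -1.73 over the alternatives run. Of the genes called in endothelial cells 35 kept sign and call after that subtraction, 24 of them lower. In stromal cells genes outside the fixed lists also kept their call, such as the Wnt-related Dkk3 (0.98) and Frzb (0.62), the transcription factor Sox4 (0.85) and the collagen gene Col24a1 (2.2) among 373 higher, and the cytokine receptor Lifr (-0.63) and vitronectin (Vtn, -0.85) among 195 lower.

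Macrophage cluster 20, led by the division genes Mki67 and Top2a, held 294 CPM of Cdkn1a, more than the mean of 127 CPM over GFPhigh macrophages, and 275 of its 288 cells were GFPhigh. A mural cluster led by Myh11 and Acta2 held 415 CPM of Cdkn1a, and 56 of its 67 cells were non-GFPhigh. An epithelial cluster of 21 cells was led by Ovgp1, Plet1 and Epcam, 85.7% of them from mouse 5. An unnamed cluster of 100 cells led by Akr1cl, Greb1 and Foxl2 came to 92% from mouse 5. Plasma cell cluster 28 held 163 non-GFPhigh and 27 GFPhigh cells, 82.1% of them from mouse 3.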
